A study of Mus musculus with 16 samples.

How the data were processed

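RNA from bone-marrow LSK cells (lineage-negative, c-Kit-positive, Sca-1-positive haematopoietic stem and progenitor cells, enriched with beads according to the labels) was sequenced from 16 individual C57BL/6 mice, 4 in each of 4 genotypes. The groups are named here WT, Asxl1Tg (genotype Asxl1Y588XTg, a transgene for a mutant form of the chromatin regulator Asxl1), Srsf2P95H (genotype Srsf2P95H/+, a mutation in 1 copy of the splicing factor gene Srsf2) and DM (both mutations). The design text of the series gives 3 double-mutant samples, whereas the labels and the table hold 4, and all 4 were used. The Asxl1Tg columns carry an abbreviated name and were assigned by elimination, since the other 3 group names in the table match the sample titles. The labels give no sex, age, batch or date.

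The authors deposited raw counts per gene symbol in 1 table of 55291 genes, with 1 column per sample, and applied no normalization. Their processing notes name FastQC, Trimmomatic 0.38, STAR 2.7.0e, HTSeq 0.11.2 and the mm10 genome. The annotation release and the strand setting are not given in the sources used here. Every value was checked to be a whole number of at least 0. Biotypes and coordinates came from GENCODE M21 (GRCm38), in which 53292 of the symbols were found and 53186 belonged to a lone gene. Total counts per sample were 82.99 to 127.6 M (megacounts).

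Genes were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr (minimum count 10), TMM scaling and a quasi-likelihood fit with robust dispersion on all 16 libraries. P-values were adjusted by Benjamini-Hochberg over the 22749 genes kept, in each of 6 comparisons (each single mutant and DM against WT, DM against each single mutant, and the interaction DM - Asxl1Tg - Srsf2P95H + WT). A gene was called at an adjusted p under 0.05. Expression is given as CPM (TMM-scaled counts per megacount of library) with the SD over 4 mice, and fold changes as log2 values with their standard error (SE). The median SE was 0.235 over all genes tested and 0.0982 over the 9452 genes above 10 CPM in Asxl1Tg versus WT. For the interaction it was 0.332 over all genes tested. The genes called in Asxl1Tg versus WT had a median absolute log2 fold change of 0.92. A call needs a change of several of these standard errors, so changes near their size were not detectable. Counting error is covered by these errors only as part of the spread between mice.

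A set of 36 gene lists, written from textbook knowledge, covered stem and progenitor cells, other blood and stromal cell types, the cell cycle, metabolism, stress, splicing, chromatin and signalling. They were tested on log2 CPM (prior count 2) with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 36 lists. They were tested again with an estimated correlation and with fry, whose directional test asks whether a list's genes move one way on balance and whose mixed test asks whether they change in either direction. Of 718 list entries, 698 matched by symbol and 10 by synonym, and 10 histone entries were not matched. For each list, members called over all genes and members called when adjusted over the list alone are given. The groups, comparisons, lists, tests and the first set of alternatives were chosen before the data were examined, as was the rule for naming genes. It took Asxl1 and Srsf2, then the 8 largest rises and 8 largest falls among called genes whose 4 and 4 libraries did not overlap and whose mean reached 2 CPM, without predicted genes. It added up to 2 called members of each list, in the order of the list tests, up to 14 genes. Where fewer than 5 genes passed, the 5 smallest p-values were given as values. A gene that the rule names is not reported here.

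The replicate numbers were tested as a possible pairing. After subtraction of group means, correlations between libraries that share a number ran from -0.293 to 0.295, and 3 of 16 libraries correlated best with their own number. The numbers were therefore not used as pairs, and the replicate block was run as an alternative. The method was tested on simulated data made from these libraries, in which the counts of each gene were drawn independently. Programmes that move many genes together between mice were thus not simulated. Changed were 200 genes, drawn from those with a mean of at least 1 CPM. Of these, 22 of 50 genes changed 1.5-fold, 34 of 50 changed 2-fold, 49 of 50 changed 4-fold and 49 of 50 changed 8-fold were found, and 10 of 164 calls were unchanged genes.

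The alternatives set in advance were DESeq2 1.42.0, limma-voom with quality weights, RLE factors, library size only, no filter, a stricter filter (1 CPM in 4 samples) and a fit on the compared groups only. They also held the replicate block, each library left out in turn, a minimum absolute log2 fold change of 1, and, for genes shared by comparisons, a split of the WT libraries. Alternatives added after seeing the data were the split of libraries into high and low Xist as a covariate, the fit without WT 4 and Srsf2P95H 2, the marker level of B cells, T and natural killer cells, eosinophils and mast cells as a covariate, the level of immediate-early genes as a covariate, and protein-coding genes only. Single named genes were not tested under the minimum fold change or the protein-coding fit. A gene that a run filtered out was not counted in that run. Each count was set against the other divisions of the same libraries into groups of equal size. Splicing itself was not measured, since the table holds counts per gene only.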

Results

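Expression of 22749 genes was compared in LSK cells of 4 WT, 4 Asxl1Tg, 4 Srsf2P95H and 4 DM mice. The title of the series asks how the Srsf2 mutation acts on leukaemia development with the Asxl1 transgene, so each mutation was examined alone, in combination and in the presence of the other. Total counts were 97.8 ± 18.7 M (megacounts) in WT, 93.6 ± 7.02 M in Asxl1Tg, 99.1 ± 6.08 M in Srsf2P95H and 120 ± 6.47 M in DM (SD, n = 4). DM libraries were deeper than those of either single mutant (exact permutation test, two-sided p = 0.0286 for each). WT 4 had the highest mean log2 CPM of B lineage genes (3.44, against -0.11 to 1.31 in the other WT libraries) and of eosinophil genes (5.99, against 0.64 to 3.64). Its immediate-early genes were the lowest of the WT libraries (3.74, against 6.31 to 7.30). Srsf2P95H 2 had the highest level of immediate-early genes (8.12). Xist, the RNA of the inactive X chromosome, was at 1566 CPM or more in WT 1, Asxl1Tg 3, Srsf2P95H 2, Srsf2P95H 3 and DM 1, and at 2.11 CPM or less in the other libraries.

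Asxl1, at chromosome 2 153345829–153404007 (GRCm38), was at 219.6 ± 7.32 CPM in WT, 228.1 ± 7.94 in Asxl1Tg, 213.9 ± 13.5 in Srsf2P95H and 225.7 ± 8.89 in DM (SD, n = 4). Srsf2, at chromosome 11 116849901–116853094, was at 204.3 ± 27.8 CPM in WT, 254.4 ± 30.4 in Asxl1Tg, 224.7 ± 26.6 in Srsf2P95H and 203.5 ± 22.9 in DM. Neither gene passed the test in a comparison, and the smallest adjusted p was that of Srsf2 in Asxl1Tg versus WT (log2 fold change 0.32, adjusted p = 0.130). The transgene is counted under Asxl1 only if its sequence maps there, and a point mutation need not change the level of Srsf2. These levels therefore show neither the expression of the transgene nor whether the labels are right.

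The first comparison asked what the Asxl1 transgene alone does to LSK cells. Evc and Evc2, adjacent genes for a ciliary protein complex of Hedgehog signalling (chromosome 5 37289098–37336894 and 37338499–37425055), were 20.8-fold and 14.5-fold higher in Asxl1Tg than in WT. Evc rose from 1.77 ± 0.874 to 36.7 ± 6.92 CPM (log2 fold change 4.38, SE 0.31, adjusted p = 4.36e-06), and Evc2 rose from 2.45 ± 1.69 to 35.4 ± 5.57 CPM. Serpinh1, a chaperone of collagen (chromosome 7 99345376–99353239), rose from 2.90 ± 0.700 to 16.2 ± 1.61 CPM. Dzip1l, a gene of the ciliary base, rose 18.7-fold from 0.166 ± 0.161 to 3.10 ± 0.728 CPM. Pxdn (peroxidasin) rose by 4.26 and Matn4 (a matrilin) by 3.61 on the log2 scale, as did Spats2 (3.32) and Pkdrej (2.71). Hmga2, an architectural chromatin protein of fetal stem cells (chromosome 10 120361275–120476469), was 4.05-fold lower (22.02 ± 3.05 and 5.45 ± 2.19 CPM). The zinc-finger gene Plag1 fell by 1.80 on the log2 scale. The other large falls were in Ccr9, a chemokine receptor of lymphoid progenitors and thymocytes (11.5-fold), Postn (periostin, 8.19-fold) and the germline helicase gene Ddx4 (5.05-fold). Lower too were Icos, a T-cell costimulator (4.11-fold), the syndecan Sdc4 (3.56-fold) and Gcsam, a germinal-centre gene (3.53-fold).

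Among the fixed lists, interferon-stimulated genes fell in Asxl1Tg, with a median log2 fold change of -0.60 and 5 of 26 called lower (20 when adjusted over the list alone). The camera test gave adjusted p = 7.86e-10, and adjusted p = 0.746 with an estimated correlation. Ifi44 and Ifit1 were 2.21-fold and 2.20-fold lower. Lymphoid-primed progenitor genes fell, with a median of -0.59 and 2 of 15 called, Ccr9 and the recombinase gene Rag2 (7 when adjusted over the list alone). Their camera test gave adjusted p = 0.000444, and adjusted p = 0.746 with an estimated correlation. DNA replication genes rose by a median of 0.33 (0 of 24 called over all genes, 17 adjusted over the list alone). MYC and ribosome biogenesis genes rose by 0.34 (0 of 23, and 15 adjusted over the list alone). Oxidative phosphorylation genes rose by a median of 0.18 (1 of 29 called, Cox5b of complex IV at 0.43, and 1 adjusted over the list alone). Glycolysis and hypoxia genes rose by a median of 0.25 (1 of 20 called, the hexokinase gene Hk2 at 0.48, and 6 adjusted over the list alone). All 4 of these lists stood at adjusted p = 0.746 with an estimated correlation. The glycolysis call was lost without both WT 4 and Srsf2P95H 2 (0.0827) and with the marker covariate (0.208). The list of DNA repair genes moved up by a median of 0.15 (camera adjusted p = 0.0142, and adjusted p = 0.804 with an estimated correlation). Its 1 called member of 24, the checkpoint kinase gene Chek2, was lower at -0.50 (1 higher and 1 lower adjusted over the list alone). The call of this list was lost with the stricter filter (0.0504) and the marker covariate (0.133). SR protein and hnRNP genes (0.10, 0 of 27 called, 0 adjusted over the list alone; camera adjusted p = 0.0223) and unfolded protein response genes (0.26, 0 of 20 called, 0 adjusted over the list alone; 0.0110) rose. Both calls were lost without WT 4 (0.311 and 0.0705) or Asxl1Tg 1 (0.0999 and 0.0852), with the stricter filter (0.0556 and 0.0538) and without both WT 4 and Srsf2P95H 2 (0.317 and 0.0906). With the marker covariate the first was reversed (0.977) and the second lost (0.269). Mitochondrially encoded genes fell by a median of -0.25 (0 of 12 called, 0 adjusted over the list alone; camera adjusted p = 0.0223), a call lost without WT 1 (0.0639), Asxl1Tg 2 (0.0549) or Asxl1Tg 4 (0.158). They took 0.721 ± 0.0901% of counts in Asxl1Tg and 0.864 ± 0.0607% in WT (SD, n = 4; exact permutation test, two-sided p = 0.0571), and RNA quality, which is not in the labels, was not tested. With an estimated correlation these 3 lists stood at adjusted p = 0.804, 0.746 and 0.804. Further called members were Hoxb8 (2.78) and Hoxb5 (0.93), homeobox genes of stem cells. Called lower were the p53 targets Trp53inp1 (-0.98) and Sesn1 (-0.59), the MHC class II gene H2-Ob (-1.23), Atf2 (-0.24) and the E-protein gene Tcf4 (-0.30).

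Markers of other cell types moved in the same comparison. T and natural killer cell genes fell by a median of -0.83 (0 of 17 called, 2 adjusted over the list alone, camera adjusted p = 0.00715), a call lost with the stricter filter (0.0606). Dendritic cell genes had a median of -0.63 (1 of 12 called, Tcf4, and 2 adjusted over the list alone) and mast cell genes -0.57 (0 of 13 called, 0 adjusted over the list alone), each at camera adjusted p = 0.0498. The dendritic call was lost without WT 2 (0.106), WT 4 (0.186), Asxl1Tg 1 (0.109) or Asxl1Tg 4 (0.0521), with the stricter filter (0.0606), with the marker covariate (0.574) and without both WT 4 and Srsf2P95H 2 (0.230). The mast cell call was lost without WT 1 (0.211), WT 2 (0.0808), WT 4 (0.154), Asxl1Tg 2 (0.105) or Asxl1Tg 4 (0.200), with the replicate block (0.0781), with the stricter filter (0.232) and without both WT 4 and Srsf2P95H 2 (0.154). Granulocyte-monocyte progenitor genes rose by a median of 0.39 (0 of 17 called, 0 adjusted over the list alone) and monocyte and macrophage genes by 0.64 (0 of 16 called, 0 adjusted over the list alone), each at camera adjusted p = 0.00298. Both calls were lost without WT 3 (0.111 and 0.128). With an estimated correlation the mast cell list stood at adjusted p = 0.781, and the other 4 at adjusted p = 0.746 with an estimated correlation. B lineage genes (median -1.52) and eosinophil genes (-2.01), both highest in WT 4, did not pass (camera adjusted p = 0.0972 and 0.137).

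In total 428 genes were called in Asxl1Tg versus WT, 255 higher and 173 lower, and 15 of 36 lists. No list was called with an estimated correlation or by fry. The count was 951 without WT 1, 137 without WT 2, 152 without WT 3, 147 without WT 4, 168 without Asxl1Tg 1, 2330 without Asxl1Tg 2, 236 without Asxl1Tg 3 and 121 without Asxl1Tg 4. It was 1776 with DESeq2, 1164 with limma-voom, 648 with the replicate block, 73 on the compared groups only, 212 without both WT 4 and Srsf2P95H 2 and 98 with the marker level of other cell types as a covariate. The calls of Evc, Evc2, Serpinh1, Dzip1l, Matn4, Spats2, Hmga2, Plag1, Ifi44 and Hoxb8 held in each alternative run, and those of the other genes named were lost in 1 or more.

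**Figure D1:**
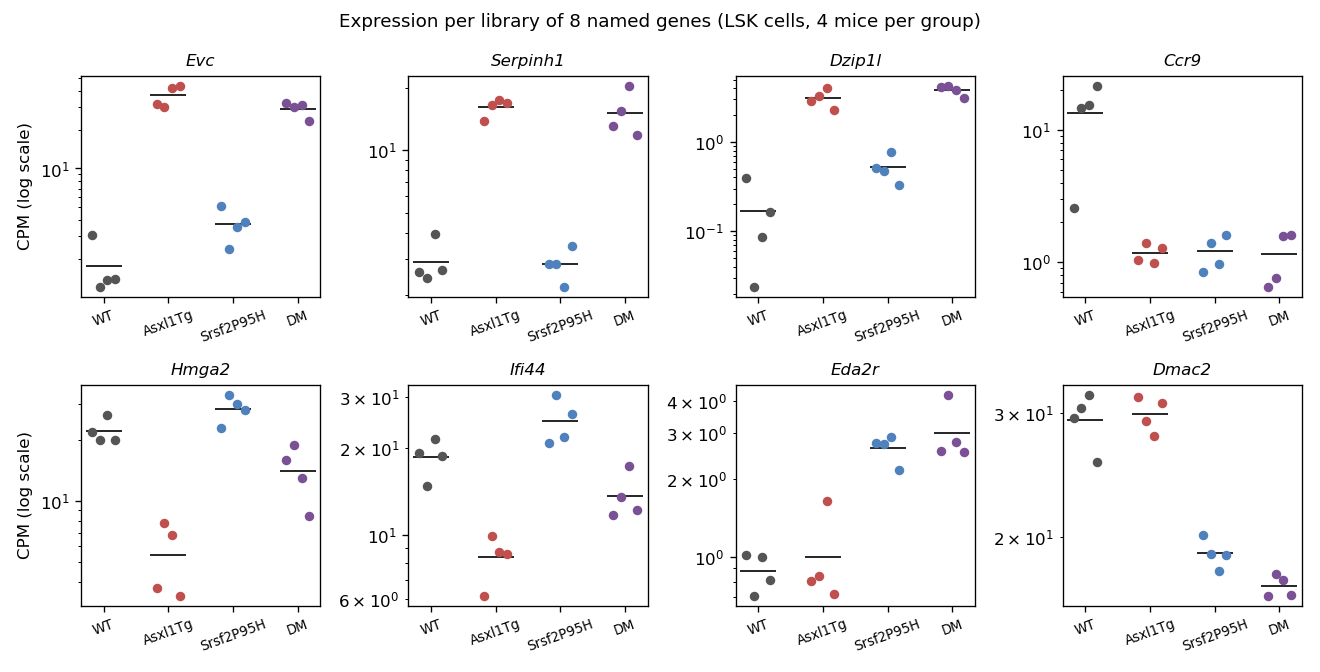
Expression per library, in CPM on a log scale, of 8 named genes in the 4 genotypes. Each point is 1 mouse and the horizontal line is the mean of 4. Evc in the 4 Asxl1Tg libraries is at 29.9 CPM or more, and in the 4 WT libraries at or below 3.07 CPM.

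The second comparison asked what the Srsf2 mutation alone does. Eda2r, a p53-inducible receptor of the tumour necrosis factor family (chromosome X 97333840–97377216), was 2.97-fold higher in Srsf2P95H than in WT (0.883 ± 0.148 and 2.63 ± 0.315 CPM). Its log2 fold change was 1.57 (SE 0.26, adjusted p = 0.0183). The cytoskeletal linker Tln2 rose by 1.54 on the log2 scale, the stress-response gene Nupr1 by 1.40, and Lypd6b by 1.30. Further rises were those of the netrin receptor gene Neo1 by 1.29, the enzyme gene Dglucy by 1.25, the antisense RNA Tnfsf13os by 1.24 and the testis proteasome subunit Psma8 by 0.96. Ccr9 was 11.2-fold lower (13.5 ± 7.91 and 1.21 ± 0.361 CPM), near its level in Asxl1Tg. Other falls were in Cmya5 (6.82-fold), the immune checkpoint gene Cd276 (3.56-fold), the actin-bundling gene Fscn1 (3.26-fold), Wdr86 (3.14-fold), Scube3 (2.93-fold), Gipc3 (2.77-fold) and Rwdd3 (2.42-fold). Hnrnpa2b1, an RNA-binding splicing regulator, rose from 752.6 ± 60.8 to 1043 ± 53.2 CPM.

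The lists with the smallest p in Srsf2P95H were those of growth, though none of their members was called over all genes. Oxidative phosphorylation genes rose by a median of 0.28 (25 of 29 called when adjusted over the list alone) and MYC and ribosome biogenesis genes by 0.37 (20 of 23 adjusted over the list alone). DNA replication genes rose by 0.34 (22 of 24 adjusted over the list alone) and cytosolic ribosomal protein genes by 0.18 (0 of 33 adjusted over the list alone). Each of these lists stood at adjusted p = 0.520 with an estimated correlation, and the ribosomal protein call was lost without both WT 4 and Srsf2P95H 2 (0.0849). Granulocyte-monocyte progenitor genes rose by a median of 0.60 (0 of 17 called, 3 adjusted over the list alone) and unfolded protein response genes by 0.51 (0 of 20 called, 12 adjusted over the list alone). Both stood at adjusted p = 0.520 with an estimated correlation. The list of SR protein and hnRNP genes rose by a median of 0.17 (1 of 27 called, Hnrnpa2b1, and 6 adjusted over the list alone), at adjusted p = 0.520 with an estimated correlation. Mitotic genes rose by 0.27 (0 of 24 called, 6 adjusted over the list alone), at adjusted p = 0.562 with an estimated correlation. T and natural killer cell genes fell by a median of -0.82 (0 of 17 called, 6 adjusted over the list alone), at adjusted p = 0.520 with an estimated correlation, and were highest in WT 4. Lymphoid-primed progenitor genes had a median of -0.64 (1 of 15 called, Ccr9, and 7 lower and 2 higher adjusted over the list alone). The list passed at camera adjusted p = 0.0468, with adjusted p = 0.592 with an estimated correlation. This call was lost without WT 2, WT 3, WT 4, Srsf2P95H 1, Srsf2P95H 3 or Srsf2P95H 4, at adjusted p from 0.0501 to 0.109. It was lost as well with the Xist covariate (0.0569), with the immediate-early covariate (0.0651) and without both WT 4 and Srsf2P95H 2 (0.0575). Mature neutrophil genes rose by a median of 0.66 (0 of 16 called, 1 adjusted over the list alone, camera adjusted p = 0.0148), at adjusted p = 0.520 with an estimated correlation, a call lost without WT 3 (0.146) and with the stricter filter (0.117). Of the p53 target list 1 of 20 was called higher, with a median of 0.27 (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0256). This call was lost without WT 1 (0.0639), WT 4 (0.0517) or Srsf2P95H 2 (0.09998), with the stricter filter (0.0942) and without both WT 4 and Srsf2P95H 2 (0.324). SRSF2 splice targets had a median of 0.07, and of -0.05 with library size only (1 of 18 called, 3 adjusted over the list alone, camera adjusted p = 0.0468), a call lost in 9 of 15 alternative runs (adjusted p up to 0.277, with the stricter filter). Glycolysis and hypoxia genes rose by 0.34 (0 of 20 called, 10 adjusted over the list alone) and DNA repair genes by 0.18 (0 of 24 called, 0 adjusted over the list alone). These 4 lists stood at adjusted p = 0.520 with an estimated correlation. Interferon-stimulated genes, lower in Asxl1Tg, had a median of 0.07 here, and of -0.04 with library size only. No member of 26 was called (2 higher adjusted over the list alone, camera adjusted p = 0.196).

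In total 115 genes were called in Srsf2P95H versus WT, 60 higher and 55 lower, and 15 of 36 lists, of which none was called with an estimated correlation or by fry. With library size only the median of all genes moved by -0.11 on the log2 scale and 217 genes were called, 40 higher and 177 lower. The count of genes was 1638 without WT 1, 26 without WT 2, 0 without WT 3, 1 without WT 4, 1 without Srsf2P95H 1, 1532 without Srsf2P95H 2, 26 without Srsf2P95H 3 and 0 without Srsf2P95H 4. It was 2448 with DESeq2, 1703 with limma-voom, 952 with the replicate block, 2 on the compared groups only, 298 without both WT 4 and Srsf2P95H 2 and 7 with the marker level of other cell types as a covariate. The call of each gene named here was lost in 1 or more alternatives.

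**Figure D2:**
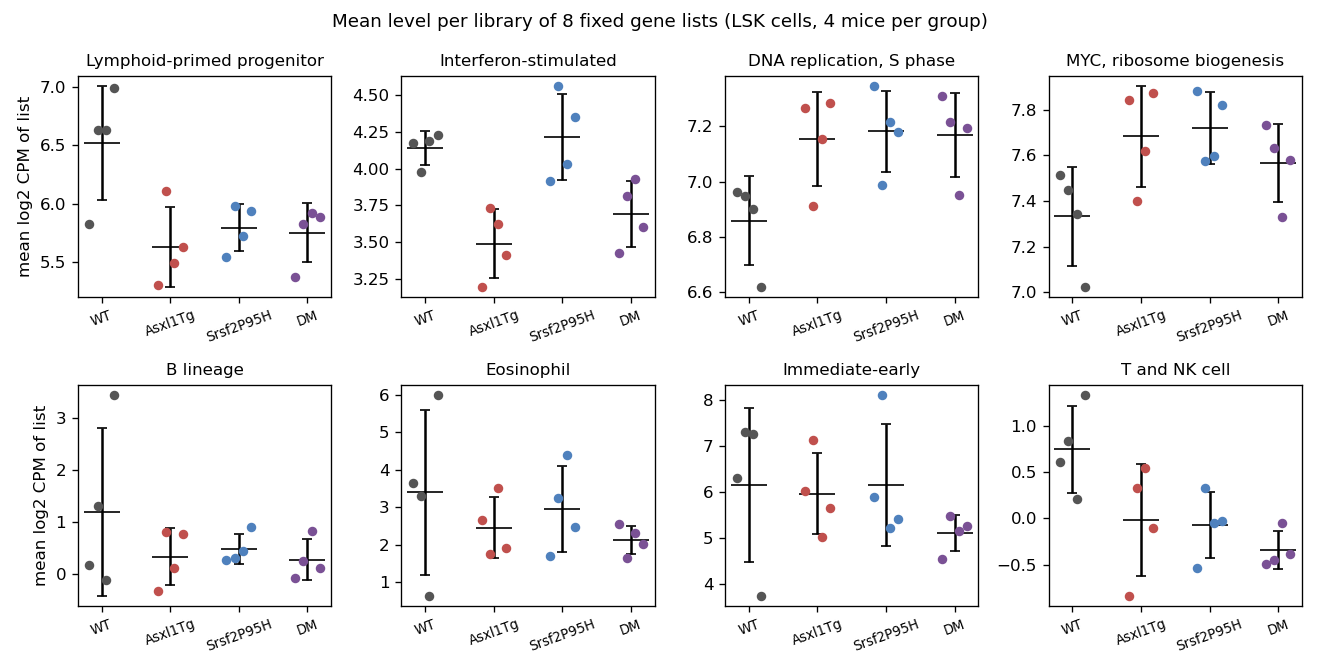
Mean log2 CPM of 8 fixed gene lists in each library, by genotype. Each point is 1 mouse, the horizontal line is the mean of 4 and the bar is 1 SD either side. Interferon-stimulated genes lie at 3.20 to 3.73 in the Asxl1Tg libraries and at 3.98 to 4.23 in the WT libraries. WT 4 lies highest for B lineage (3.44) and eosinophil genes (5.99).

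The third comparison set both mutations against neither. Evc in DM, at 29.1 ± 3.96 CPM, was 16.5-fold above WT (SE 0.30 on the log2 scale, adjusted p = 7.57e-06). Dzip1l rose by 4.53 and Evc2 by 3.43 on the log2 scale. Pxdn (3.89) and Matn4 (3.33) rose as well, with Armh4 (3.22), the magnesium channel gene Trpm6 (2.75) and Pawr, a regulator of apoptosis (2.68). Chl1, a neural adhesion molecule, was 21.9-fold lower (4.64 ± 3.89 and 0.210 ± 0.0431 CPM), and Ccr9 11.7-fold lower. The lymphoid transcription factor gene Lef1 was 7.83-fold lower, and Cmya5, Stum, Map3k19, the antisense RNA Kdm6bos and Plag1 were 4.79-fold to 7.30-fold lower. The log2 fold change of Lef1 ran from -3.30 to -1.21 over the runs, and its call was lost in 2 of 19 alternative runs. Stem-cell genes rose by a median of 0.26 (5 of 23 called, 7 adjusted over the list alone). Among them were Hoxb5 (1.35) and Esam, an adhesion molecule of stem cells (0.74). The stem-cell list stood at camera adjusted p = 0.00244 and at adjusted p = 0.611 with an estimated correlation. Of the p53 target list 5 of 20 were called higher and none lower (5 adjusted over the list alone). The p53 list stood at camera adjusted p = 0.0382, at adjusted p = 0.611 with an estimated correlation and at adjusted p = 0.04935 with fry. The median of that list was 0.06 with TMM and -0.03 with library size only, and its camera call was lost without WT 1 (0.0600), WT 4 (0.0809) or DM 2 (0.0751). It was lost as well with the stricter filter (0.103), with the marker covariate (0.0826) and without both WT 4 and Srsf2P95H 2 (0.150).

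Growth lists also rose in DM. Oxidative phosphorylation genes had a median of 0.26 (3 of 29 called, with Ndufb5 at 0.40 and Atp5c1 at 0.29, and 14 adjusted over the list alone). DNA replication genes had 0.32 (2 of 24, the thymidylate synthase gene Tyms at 0.41 and the helicase subunit Mcm4 at 0.37, and 22 adjusted over the list alone). Cytosolic ribosomal proteins had 0.21 (1 of 33, Rpl27 at 0.32, and 7 adjusted over the list alone). Granulocyte-monocyte progenitor genes had 0.49 (3 of 17, with the chaperone Calr at 0.65 and the transcription factor Gfi1 at 0.46, and 3 adjusted over the list alone). Each of these lists stood at adjusted p = 0.611 with an estimated correlation. Mitotic genes had a median of 0.28 (1 of 24, the survivin gene Birc5 at 0.40, and 0 adjusted over the list alone), at adjusted p = 0.611 with an estimated correlation. T and natural killer cell genes fell by a median of -1.18 (3 of 17 called, and 10 lower and 1 higher adjusted over the list alone), at adjusted p = 0.611 with an estimated correlation and adjusted p = 0.0494 with fry. The T-cell kinase gene Lck was lower at -0.93 and the natural killer receptor gene Ncr1 fell from 0.664 ± 0.754 to 0.0321 ± 0.0180 CPM. Interferon-stimulated genes fell by a median of -0.40 (5 of 26 called, with Ifit1 at -1.02 and Ifit3 at -1.49, and 6 lower and 1 higher adjusted over the list alone). Lymphoid-primed progenitor genes fell by -0.73 (3 of 15 called, and 8 lower and 2 higher adjusted over the list alone), and both lists stood at adjusted p = 0.611 with an estimated correlation. B lineage genes, which were highest in WT 4, had a median of -1.73 (1 of 15 called, 2 adjusted over the list alone) and eosinophil genes -2.46 (0 of 9 called, 6 adjusted over the list alone). Neither of these lists passed (camera adjusted p = 0.0600 and 0.115).

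In total 2135 genes were called in DM versus WT, 1058 higher and 1077 lower (551 and 1492 with library size only), and 20 of 36 lists. With an estimated correlation no list was called, and fry called 3 of the 36. Of the called genes 1576 were protein-coding, and 465 noncoding genes were lower. The count was 1187 without WT 2, 677 without WT 3, 1040 without WT 4, 586 without DM 1, 592 without DM 2 and 742 without DM 4. It was 3909 with DESeq2, 4311 with limma-voom and 823 with the marker level of other cell types as a covariate. Of the genes named, Evc, Evc2, Dzip1l, Pxdn, Matn4, Armh4, Trpm6, Chl1, Ccr9, Cmya5, Map3k19, Plag1, Hoxb5 and Esam were called in each alternative run that tested them. The minimum fold change, which Esam does not reach, was not among these runs.

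The genes of the single mutants were then sought among each other and in DM. Both single mutants shared 17 called genes against WT, 16 of them in the same direction (11 higher and 5 lower), where independent lists would share 0.673 higher and 0.418 lower genes. Because the same WT libraries serve both comparisons, log2 fold changes correlate without any shared effect. The correlation across 14339 genes, which are not independent replicates, was 0.562, and simulations with no effect of either mutation gave 0.494. They gave 0 shared calls as well. With no gene changed few calls arise at all, so this cannot judge the 16 shared genes. With the WT libraries divided 2 and 2 between the comparisons, a median of 1 gene was shared (range 0 to 7) and the correlation was 0.118 to 0.263. In these divisions Srsf2P95H called 2291, 78, 8, 0, 1 and 0 genes against its 2 WT libraries. In most of them few or no genes could therefore be shared, and the median of 1 cannot judge the 16 genes. Of the 428 genes called in Asxl1Tg versus WT, 248 were called in DM versus WT, all 248 in the same direction. Of the 115 called in Srsf2P95H versus WT, 101 were called in DM versus WT, 100 in the same direction. These comparisons share the WT libraries as well, so agreement in direction is expected without a shared effect. With the WT libraries divided 2 and 2, Asxl1Tg and DM shared a median of 32.5 called genes (range 16 to 53), with correlations of 0.254 to 0.365 against 0.672 with the WT libraries shared. Srsf2P95H and DM shared a median of 4 (range 0 to 57), with correlations of 0.240 to 0.386 against 0.688. In these divisions a median of 77 genes was called in Asxl1Tg and of 4.5 in Srsf2P95H, each against 2 WT libraries. So few calls limit how many genes can be shared, and the shared numbers cannot be set against 248 and 101. The number shared in the same direction by the single mutants was 391 without WT 1, 5 without WT 2, 0 without WT 3, 0 without WT 4, 10 without Asxl1Tg 1 and 454 without Asxl1Tg 2. It was 0 without Srsf2P95H 1, 107 without Srsf2P95H 2, 5 without Srsf2P95H 3, 0 without Srsf2P95H 4 and 144 with the replicate block. In the runs that shared 0 genes, Srsf2P95H versus WT itself called at most 1 gene.

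The fourth comparison, DM versus Asxl1Tg, asked what the Srsf2 mutation adds in cells with the transgene. Dmac2, a mitochondrial assembly factor (chromosome 7 25619414–25625551), fell from 29.9 ± 1.72 to 17.1 ± 0.603 CPM (log2 fold change -0.81, SE 0.08, adjusted p = 2.79e-04). It stood at 19.0 ± 0.928 CPM in Srsf2P95H. Galns, a lysosomal sulfatase (chromosome 8 122578242–122611463), was 2.02-fold lower (26.6 ± 2.63 and 13.2 ± 2.13 CPM), and Kctd17 fell by 0.78 on the log2 scale. Other falls were in Gper1, an oestrogen receptor of the membrane (2.79-fold), Fscn1 (2.45-fold), the Wnt receptor Fzd8 (2.05-fold), the kinesin Kifc3 (1.94-fold) and Spata5l1 (1.72-fold). Eda2r was 3.01-fold and Lypd6b 3.05-fold higher in DM, as they were in Srsf2P95H against WT. Bpifb5 (1.77), the chemokine receptor gene Cxcr1 (1.63), Rbm44 (1.53), the prostaglandin synthase Ptgds (1.39) and Fhit (1.28) rose on the log2 scale. Hmga2, low in Asxl1Tg, was 2.58-fold higher in DM, at 14.03 ± 4.40 CPM, and Bgn (biglycan, a matrix proteoglycan) rose from 19.4 ± 3.22 to 46.8 ± 11.1 CPM.

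By list, 3 of 20 p53 targets were called higher and none lower in DM than in Asxl1Tg (7 adjusted over the list alone), among them Eda2r and the cyclin gene Ccng1 (0.54). The p53 list stood at camera adjusted p = 0.0445, at adjusted p = 0.897 with an estimated correlation and at adjusted p = 0.0306 with fry. Its median was 0.04, and -0.03 with library size only, and its camera call was lost without Asxl1Tg 3 (0.0604) or DM 2 (0.1104). It was lost as well with the replicate block (0.0730), with the stricter filter (0.112) and without both WT 4 and Srsf2P95H 2 (0.105). Cytosolic ribosomal protein genes rose by a median of 0.17 (1 of 33 called, Rpl22 at 0.40, and 1 adjusted over the list alone). Mitotic genes rose by 0.22 (0 of 24 called, 0 adjusted over the list alone), and both lists stood at adjusted p = 0.997 with an estimated correlation. Mitochondrially encoded genes had a median of 0.33 (0 of 12 called, 4 adjusted over the list alone). They stood at camera adjusted p = 0.00365, a call lost without DM 1 (0.0694), and at adjusted p = 0.997 with an estimated correlation. Immediate-early genes fell by a median of -1.04 (0 of 21 called, 0 adjusted over the list alone, camera adjusted p = 0.0124), at adjusted p = 0.997 with an estimated correlation, a call lost without Asxl1Tg 2 (0.177) or DM 1 (0.0661). Interferon-stimulated genes rose by a median of 0.21 (0 of 26 called, 2 adjusted over the list alone, camera adjusted p = 0.0124), a call lost without Asxl1Tg 1 (0.0989) or DM 3 (0.0967). Stem-cell genes rose by 0.18 (0 of 23 called, 0 adjusted over the list alone, camera adjusted p = 0.0169), a call lost without Asxl1Tg 1 (0.183) or DM 3 (0.197) and with the stricter filter (0.0522). Both lists stood at adjusted p = 0.997 with an estimated correlation. Histones (0.23, 0 of 9 called), genes recurrently mutated in myeloid neoplasms (0.05, and -0.02 with library size only; 0 of 29), SRSF2 splice targets (0.06, and -0.02; 1 of 18) and mast cell genes (0.50, 0 of 13) were the other called lists, each lost in 3 or more alternative runs. Atf2 (0.37), on the list of genes spliced differently with mutant SRSF2, was higher. In total 245 genes were called, 193 higher and 52 lower (32 and 54 of 86 with library size only), and 11 of 36 lists. With an estimated correlation no list was called, and fry called 3 of the 36. Without DM 1, 7 lists were called, 6 of the 11 among them. The count of genes was 10 without Asxl1Tg 1, 17 without Asxl1Tg 4, 24 without DM 1, 25 without DM 2, 118 without DM 3 and 28 without DM 4. It was 135 with RLE factors, 17 on the compared groups only, 240 with the replicate block, 655 without both WT 4 and Srsf2P95H 2, 1135 with DESeq2 and 1112 with limma-voom. The calls of Dmac2, Galns, Kctd17 and Bgn held in each alternative run. The minimum fold change, which Dmac2 and Kctd17 do not reach, was not applied to single genes.

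The fifth comparison, DM versus Srsf2P95H, asked what the transgene adds in cells with the Srsf2 mutation. Serpinh1 rose from 2.83 ± 0.515 to 15.2 ± 3.79 CPM (log2 fold change 2.42, SE 0.20, adjusted p = 1.84e-05), with Fkbp10, another collagen-folding factor (4.13-fold). Evc was 7.82-fold higher (3.71 ± 1.12 and 29.1 ± 3.96 CPM), Dzip1l 7.31-fold, Evc2 6.62-fold, Spats2 6.32-fold, the adhesion molecule Kirrel 3.70-fold and Cd276 3.08-fold. Interferon-stimulated genes fell by a median of -0.54 (2 of 26 called, Ifit1 at -1.20 and Ifi44 at -0.85, and 13 adjusted over the list alone). This list stood at camera adjusted p = 1.70e-14 and at adjusted p = 0.748 with an estimated correlation. Chek2 (-0.50), the autophagy kinase gene Ulk1 (-0.54) and Socs2, an inhibitor of cytokine signalling (-1.19), were lower. Stem-cell genes had a median of 0.24 (0 of 23 called, 0 adjusted over the list alone). They stood at camera adjusted p = 0.000834, a call lost without DM 3 (0.163), and at adjusted p = 0.958 with an estimated correlation. Immediate-early genes, highest in Srsf2P95H 2, fell by a median of -1.33 (0 of 21 called, 0 adjusted over the list alone, camera adjusted p = 3.51e-05), at adjusted p = 0.958 with an estimated correlation, a call lost without Srsf2P95H 2 (0.166). MYC and ribosome biogenesis genes (-0.15, 0 of 23 called), SR protein and hnRNP genes (-0.08, 0 of 27), cholesterol synthesis genes (0.12, 0 of 20) and histones (0.14, 0 of 9) were the other called lists, with 0 members of each adjusted over the list alone. They were lost in 2, 3, 5 and 9 of 15 alternative runs, MYC without Srsf2P95H 1 (0.0719) or DM 3 (0.163), and stood at adjusted p = 0.958 with an estimated correlation. In total 56 genes were called, 49 higher and 7 lower, and 7 of 36 lists, none with an estimated correlation or by fry. Without DM 3 the number of lists was 4. The count of genes was 24 without Srsf2P95H 1, 34 without Srsf2P95H 2, 20 without Srsf2P95H 4, 23 without DM 2 and 24 without DM 3. It was 62 with the replicate block, 26 without both WT 4 and Srsf2P95H 2, 234 with DESeq2 and 103 with limma-voom. The calls of Evc, Evc2, Serpinh1, Fkbp10, Kirrel and Chek2 held in each alternative run. The minimum fold change, which Chek2 does not reach, was not one of them.

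Comparisons without a common library show each mutation in both backgrounds. Asxl1Tg versus WT and DM versus Srsf2P95H had 38 called genes in common, all 38 in the same direction, against 0.602 by chance for independent lists. All 56 genes called in the second had the same sign in the first, and 346 of the 428 called in the first (80.8%) had the same sign in the second, where their median change in that direction was 0.25. Srsf2P95H versus WT and DM versus Asxl1Tg had 26 in common, 25 in the same direction, against 0.635 by chance, and 227 of the 245 genes called in the second had the same sign in the first. Of the 115 called in the first, 107 (93.0%) had the same sign in the second, with a median change there of 0.32. Their medians in the first, 0.92 and 0.66, are raised by the choice of genes called there, so the pairs of medians do not measure a loss of effect. Over all genes above 1 CPM the correlation of the log2 changes in both backgrounds was 0.229 for the transgene and 0.225 for the Srsf2 mutation.

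The interaction asked whether the effect of both mutations differs from the sum of the effects of each on the log2 scale. No gene passed with edgeR (0 of 22749), with 2670 genes at an unadjusted p under 0.05. DESeq2 called 53 genes, limma-voom 4 and the replicate block 0, and edgeR called 7 without WT 1 and 1 without WT 2. The smallest p belonged to Serpina3g, a serpin of immune cells, at 46.8 ± 4.57 CPM in WT, 74.9 ± 7.86 in Asxl1Tg, 66.4 ± 7.80 in Srsf2P95H and 55.3 ± 5.49 in DM. Its interaction was -0.95 (SE 0.14, adjusted p = 0.0851). Next were the melanocortin receptor gene Mc5r (0.80), Matn4 (-2.87), Rbm44 (2.54) and Tmprss4 (3.83), with adjusted p from 0.245 to 0.247. MYC and ribosome biogenesis genes lay below the sum by a median of -0.49 (0 of 23 called, 16 adjusted over the list alone, camera adjusted p = 5.36e-14). DNA replication genes lay below it by -0.34 (0 of 24 called, 0 adjusted over the list alone, camera adjusted p = 1.06e-08), and both lists stood at adjusted p = 0.805 with an estimated correlation. Lymphoid-primed progenitor genes lay above it by a median of 0.65 (0 of 15 called, 2 adjusted over the list alone, camera adjusted p = 0.00923), at adjusted p = 0.805 with an estimated correlation. Of 36 lists 14 were called, none with an estimated correlation or by fry. The same WT libraries enter both single-mutant effects, so an offset of these libraries alone would move the interaction the opposite way.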

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

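The tests on Evc, on the exchange of WT 1 and Asxl1Tg 2 and on noncoding genes were chosen only after the results were seen. The comparison with other divisions of the libraries was set in advance.

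Each count was set against the 35 divisions of its 8 libraries into 4 and 4, the real one included. For DM versus WT 1 of 35 gave as many genes (2135, highest other 6), for DM versus Asxl1Tg 1 of 35 (245, highest other 1) and for DM versus Srsf2P95H 1 of 35 (56, highest other 0). For these 3 a chance division was argued against, at the lowest share that 35 divisions can give and without adjustment for the number of tests. For Asxl1Tg versus WT 2 of 35 gave as many (428, highest other 1407) and for Srsf2P95H versus WT 2 of 35 (115, highest other 169, the exchange of WT 4 and Srsf2P95H 2), so a chance division was not excluded. For lists a chance division was argued against in none of these comparisons. As many lists came from 17 of 35 divisions for Asxl1Tg versus WT (15, highest other 23) and 19 of 35 for Srsf2P95H versus WT (15, highest other 22). They came from 4 of 35 for DM versus WT (20, highest other 22), 17 of 35 for DM versus Asxl1Tg (11, highest other 19) and 32 of 35 for DM versus Srsf2P95H (7, highest other 20). For the interaction, 60 of 60 drawn divisions gave at least 0 genes (0, highest other 0) and 35 of 60 gave as many lists (14, highest other 23). For genes called the same way in both single mutants 1 of 60 drawn divisions gave as many (16, highest other 11). These draws also break up the WT group that both comparisons share. They therefore cannot tell a shared effect from the use of the same WT libraries.

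Evc and Evc2 were high in both groups with the transgene. RNA from stromal or endothelial cells, which the selection of LSK cells would remove, was argued against by the 17 tested genes of that list, with a median log2 change of -0.29 in DM versus Srsf2P95H (quartiles -0.73 and 0.07). Single collagen genes decide less, as Col1a1 was at 3.72 ± 4.75 CPM in WT, 23.9 ± 20.8 in Asxl1Tg, 32.5 ± 53.1 in Srsf2P95H and 18.2 ± 17.5 in DM, and Col1a2 at 6.76, 16.9, 27.2 and 16.4 CPM (SD, n = 4; neither called in any comparison). A local effect at the locus, such as an insertion near it, stays open, as 1 of 20 other tested genes within 1 Mb of Evc rose in both transgenic groups against WT, Nsg1 (1.73 and 1.23), against 183 of all genes tested (one-sided Fisher's exact p = 0.147), the neighbours had medians of 0.03 and -0.07 and the site of the transgene is not in the labels. An effect of the mutant Asxl1 protein was not tested and stays open.

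The division that exchanged WT 1 and Asxl1Tg 2 called 1407 genes, several times the real 428, and the second highest other division called 1, which points to a structure of the samples other than genotype. A swap of their labels was argued against, since 8 of 8 genes named as higher in DM than in Srsf2P95H were also higher in Asxl1Tg 2 than in WT 1. Among them, Evc stood at 29.9 CPM or more in all Asxl1Tg libraries and at 3.07 CPM or less in all WT libraries. A spread between mice in growth and lineage programmes that crosses the genotypes may be a source and could not be settled, as 10 of 15 called lists had both libraries in the opposite order to their groups (two-sided exact binomial p = 0.302). A split into libraries with high and low Xist parts WT 1 (2173 CPM) from Asxl1Tg 2 (1.73 CPM). The exchange places both libraries with high Xist in this comparison, WT 1 and Asxl1Tg 3 (1566 CPM), on the same side. With that split as a covariate of the real division, 552 genes were called in Asxl1Tg versus WT. Whether the Xist split underlies the higher count of the exchange was not tested, and age is not in the labels.

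In DM versus WT 465 of 7671 noncoding genes were lower and 35 higher, while 580 coding genes were lower and 996 higher. The greater depth of the DM libraries was argued against, since 421 noncoding genes were lower with every library thinned to the smallest total, 385 of the 465 among them, though the called genes of all kinds moved from 1058 higher and 1077 lower to 1278 and 943. Genomic DNA in the WT libraries was argued against only as a source of falls as large as those called. The summed level of 1997 olfactory and vomeronasal receptor genes had a log2 ratio of DM to WT of -0.0376 (SE 0.17). The noncoding genes that were lower had a median of -1.06, which is enlarged by the choice of called genes. Over all noncoding genes tested, the median was -0.49 for those that overlap a coding gene and -0.09 for those that overlap none. A DNA background of the size of the latter is not excluded, and the receptor level was highest in WT 4 (38.3 CPM). More unspliced transcripts of coding genes in the WT libraries are a candidate explanation. The median log2 change of noncoding genes that overlap a coding gene was below that of those that overlap none (difference -0.40, bootstrap SE 0.0142). The bootstrap resampled genes, so its SE holds no spread between mice and does not measure the precision of the difference between the groups. Antisense and unconfirmed genes took 0.559 ± 0.0903% of counts in WT and 0.384 ± 0.0480% in DM (SD, n = 4; exact permutation test, two-sided p = 0.0286). They took 0.475 ± 0.0731% in Asxl1Tg and 0.421 ± 0.0461% in Srsf2P95H, and WT 4 was the highest library (0.690%). A share below that of WT was thus not particular to DM. Whether RNA quality, handling or the mutations underlie this was not tested, and the strand setting of the counts is not known.

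Libraries far from the other 3 of their group were found in 25 of the 508 groups of 4 examined (4.92%), about the 1 in 20 that chance gives. Higher than the rest were Asxl1 in Srsf2P95H 3 (234 CPM), Bgn in WT 3 (22.2 CPM), Evc in WT 1 (3.07 CPM), Nupr1 in DM 3 (9.43 CPM), and Psma8 in Srsf2P95H 1 (13.25 CPM). So were Trp53inp1 in DM 3 (72.5 CPM) and Trpm6 in WT 1 (1.37 CPM). Lower than the rest were Cox5b in Srsf2P95H 2 (103.4 CPM) and in DM 3 (93.7 CPM), Icos in DM 2 (0.328 CPM), Ifit1 in WT 2 (6.55 CPM), and Lck in DM 1 (10.3 CPM). So were Mcm4 in WT 4 (208.8 CPM), Postn in WT 1 (0.658 CPM), Rag2 in Srsf2P95H 1 (2.04 CPM), Rbm44 in Asxl1Tg 2 (0.81 CPM) and Tnfsf13os in Asxl1Tg 4 (3.57 CPM). Among list means in log2 CPM, stem-cell genes in DM 3 (5.41), SR protein and hnRNP genes in Asxl1Tg 1 (8.30), mitochondrially encoded genes in DM 1 (5.825) and quiescence genes in Asxl1Tg 2 (5.61) were higher. Lymphoid-primed progenitor genes in DM 1 (5.38), SR protein and hnRNP genes in WT 4 (7.915), SRSF2 splice targets in Srsf2P95H 3 (6.44) and cytosolic ribosomal proteins in WT 4 (9.31) were lower.

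The effect of 1 mutation differed with and without the other, by the interaction test at the preset correlation, for 14 lists, none of which passed with an estimated correlation or by fry. Their adjusted p-values were 5.36e-14 for MYC and ribosome biogenesis, 1.06e-08 for DNA replication, 1.53e-06 for oxidative phosphorylation, 0.000145 for SR protein and hnRNP genes, 0.000378 for the unfolded protein response, 0.000378 for glycolysis and hypoxia, 0.000398 for granulocyte-monocyte progenitors and 0.00122 for monocytes and macrophages, all with negative medians. They were 0.00923 for lymphoid-primed progenitors, 0.0191 for mast cells and 0.0219 for mitochondrially encoded genes, with positive medians, and 0.0191 for immediate-early genes, 0.0191 for DNA repair and 0.0319 for mature neutrophils, with negative medians. Apart from those 2 tests, 8 of the 14 held in each of 23 alternative runs. Lost were mature neutrophils in 10 of 23 runs (adjusted p up to 0.329, without WT 3), mast cells in 8 of 22 (up to 0.1102, without WT 1), mitochondrially encoded genes in 8 of 23 (up to 0.432, without DM 1), DNA repair in 5 of 23 (up to 0.176, without DM 3) and monocytes and macrophages in 1 of 23 (0.0657, without WT 3). Immediate-early genes were lost in 6 of 22 (up to 0.811, without WT 4) and reversed in 1, without both WT 4 and Srsf2P95H 2 (0.0147). The same WT libraries enter both single-mutant effects and the interaction. An offset of these libraries alone would move the single-mutant effects one way and the interaction the other. As many lists came from 35 of 60 drawn divisions, so a chance division was not excluded for these lists.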

How the results depend on the processing

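The covariates, the fit without WT 4 and Srsf2P95H 2 and the fit on protein-coding genes were chosen only after the results were seen. All other alternatives were set in advance. Counts of genes are given in the order Asxl1Tg versus WT (428), Srsf2P95H versus WT (115), DM versus WT (2135), DM versus Asxl1Tg (245), DM versus Srsf2P95H (56) and the interaction (0), as far as they moved by over 1.5 times. With DESeq2 they were 1776, 2448, 3909, 1135, 234 and 53, and with limma-voom 1164, 1703, 4311, 1112, 103 and 4. With the replicate block the first 2 were 648 and 952, the other 4 staying at 2288, 240, 62 and 0. A fit on the compared groups only, which has fewer samples, gave 73 for the first, 2 for the second and 17 for DM versus Asxl1Tg. RLE factors gave 135 for DM versus Asxl1Tg, library size only 217 for Srsf2P95H versus WT and 86 for DM versus Asxl1Tg, the absence of a filter 101 for DM versus Asxl1Tg and 1 for the interaction, and the stricter filter 202 for Srsf2P95H versus WT. The minimum fold change, which removes genes by construction, gave 200, 39, 782 and 43 for the first 4. Protein-coding genes only gave 797, 1055 and 391 for Asxl1Tg versus WT, Srsf2P95H versus WT and DM versus Asxl1Tg. The marker level of other cell types as a covariate gave 98, 7 and 823 for the first 3, the Xist covariate 56 for Srsf2P95H versus WT and the immediate-early covariate 36 for DM versus Srsf2P95H. Without WT 4 and Srsf2P95H 2 the counts were 212 for Asxl1Tg versus WT, 298 for Srsf2P95H versus WT, 655 for DM versus Asxl1Tg and 26 for DM versus Srsf2P95H. Leaving out 1 library gave 121 to 2330, 0 to 1638, 586 to 2660, 10 to 266, 20 to 48 and 0 to 7 genes. Except where stated, the cause was not tested.

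Of the lists called (15, 15, 20, 11, 7 and 14), an estimated correlation kept 0 in all 6 comparisons. Over all 36 lists fry called 0, 0, 3, 3, 0 and 0, and it kept 5 of the lists that camera called. The stricter filter called 9 in Asxl1Tg versus WT and 6 in DM versus Asxl1Tg, and the replicate block 17, 16, 21, 8, 6 and 14. Leaving out 1 library gave 13 to 18, 14 to 18, 17 to 22, 7 to 11, 4 to 9 and 11 to 16. The direction of 3 lists reversed. They were SR protein and hnRNP genes with the marker level of other cell types as a covariate in Asxl1Tg versus WT (adjusted p = 0.977) and DM versus WT (0.943), and immediate-early genes in the interaction without WT 4 and Srsf2P95H 2 (0.0147), and the cause was not tested. Lists that compose a covariate were not tested under it.

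The genes shared in the same direction by both single mutants (16) were 540 with DESeq2, 291 with limma-voom, 144 with the replicate block, 37 without WT 4 and Srsf2P95H 2, 4 with the marker covariate, 25 with the immediate-early covariate, 150 among protein-coding genes, 7 with the minimum fold change and a median of 1 with divided WT libraries. Leaving out 1 library gave 0 to 454. In most divisions of the WT libraries, and in the runs that gave 0, few or no genes were called in Srsf2P95H versus WT, which limits these numbers. Of 110 calls of named genes, 34 held in every alternative that tested them and 76 were lost in 1 or more, and no named gene reversed. Neither the minimum fold change nor the protein-coding fit was applied to single genes. Changes of 1.5-fold were found for 22 of 50 simulated genes, which limits what the smaller counts exclude.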

Other observations

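The camera test was set in advance. The use of fry's mixed test, and the choice of the lists and values to print here, were made only after the results were seen.

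Hox and cofactor genes moved in both directions. The mixed test of fry, which takes changes either way, passed 14 of 36 lists in Asxl1Tg versus WT and 20 of 36 in DM versus WT, so a pass is not particular to the lists given here. In Asxl1Tg versus WT 2 of 17 were called higher (4 higher and 2 lower adjusted over the list alone), with a median of 0.05 and fry's mixed adjusted p = 2.80e-05, and in DM versus WT 4 of 17 were called higher (4 higher and 2 lower adjusted over the list alone), with a median of 0.07, which was -0.02 with library size only, and a mixed adjusted p = 4.39e-06. Neither passed the directional test of camera (adjusted p = 0.325 and 0.270). BCL2 family and caspase genes had 0 of 18 called in Asxl1Tg versus WT (2 higher and 1 lower adjusted over the list alone; mixed adjusted p = 0.00144) and 2 higher and 1 lower in DM versus WT (4 and 2 adjusted over the list alone; mixed adjusted p = 0.000400).

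In DM versus WT the remaining lists that passed at the preset correlation were replication-dependent histones (median 0.31, 3 of 9 higher), the unfolded protein response (0.36, 2 of 20 higher), DNA repair (0.17, 3 of 24 higher and 1 lower), glycolysis and hypoxia (0.28, 3 of 20 higher and 1 lower), MYC and ribosome biogenesis (0.22, 0 of 23), cholesterol synthesis (0.20, 0 of 20), SR protein and hnRNP genes (0.10, 2 of 27 higher), megakaryocytes (0.28, 2 of 17 higher), immediate-early genes (-1.26, 0 of 21) and inflammatory genes (-0.47, 0 of 20). With an estimated correlation none passed, at adjusted p from 0.611 to 0.697. By fry none of these passed either. Apart from those 2 tests, histones held in all 15 alternative runs. Megakaryocytes were lost in 9 of 15 (adjusted p up to 0.126, without WT 3), inflammatory genes in 5 of 15 (up to 0.403, with the immediate-early level as a covariate) and immediate-early genes in 2 of 14 (0.129 without WT 2 and 0.117 without WT 3). With the marker level of other cell types as a covariate the calls of MYC and ribosome biogenesis (0.355) and the unfolded protein response (0.0892) were lost, in 1 of 15 runs each, as were those of glycolysis and hypoxia (0.276; 4 of 15) and cholesterol synthesis (0.205; 3 of 15). SR protein and hnRNP genes were lost in 6 of 15 and reversed in that run (0.943), and DNA repair was lost with the stricter filter only (0.0503). Polycomb and ASXL-BAP1 complex genes (median 0.02, 1 of 29 higher and 1 lower; camera adjusted p = 0.866), genes recurrently mutated in myeloid neoplasms (0.12, 1 of 29 lower; 0.160), erythroid genes (-0.30, 0 of 20; 0.655), dendritic cell genes (-0.59, 3 of 12 lower; 0.0600), MHC class II genes (-0.02, 1 of 11 lower; 0.595), quiescence genes (-0.11, 0 of 16; 0.593) and mast cell genes (-0.47, 1 of 13 higher; 0.866) did not pass. For mature neutrophil genes the median was 0.10 and the mean -0.46, and for monocyte and macrophage genes the median was -0.15 while the camera direction was up (adjusted p = 0.222 for each).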
